A study of Mus musculus with 6 samples.

How the data were processed

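Liver RNA was sequenced from 6 male wild-type C57BL/6J mice, 3 after a 4 h fast and 3 after a 16 h fast, with 1 library per mouse. Per the labels' protocols, total RNA was taken with TRIzol and a spin column that included a DNase step, and a commercial provider made and sequenced the libraries. The authors trimmed reads with Trimmomatic, looked at their quality with FastQC, aligned them with STAR to the mouse build GRCm38 (mm10) and counted them per gene with HTSeq, per the submitters' processing notes and the series' design text. They name DESeq2 for their own comparison. Tool versions, the annotation release, the strand setting and the read layout are not given in the sources used here.

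The deposited values are whole-number counts per Ensembl gene, 1 table per library and not normalised by the authors. Each table has 55471 gene lines and 5 summary lines. The summary lines name no gene and stayed out of library sizes and tests. Reads outside any gene made up 6.44% to 7.14% of the tallied reads of a library and reads that hit more than 1 gene 5.78% to 6.60%. The categories for multi-mapped and unaligned reads were at 0 in all 6 tables. Reads from near-identical genes were therefore dropped before counting, are not tallied or were counted at 1 of their places, and which of these holds cannot be read from the tables. Values of multigene families are uncertain for that reason.

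Gene symbols, positions, exon lengths and GC content came from the GENCODE M21 annotation of GRCm38 (Ensembl release 96), in which 55144 of the 55471 identifiers (99.41%) were found. The release behind the counts is not stated, so the positions printed are those of M21. A read that falls in exons of more than 1 gene is not assigned to either, and without a stated strand setting this also holds for antisense genes. Of 54 protein-coding genes with at least 90% of their exon bases under an antisense gene, 44 (81.5%) had 0 counts in all libraries. The same was true of 188 of 215 (87.4%) under a gene on the same strand, and of 4492 of 15355 (29.3%) without overlap. Overlap is therefore given beside each gene with a printed change in which it covers at least 15% of exon bases.

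Library depth was between 15173653 and 26572532 counts assigned to genes. A count of 0 was read as an upper limit of 3 counts, which is 0.0488 CPM over the 4 h libraries, 0.047 CPM over the 16 h libraries and 0.0239 CPM over all 6. These limits cover counting error only, since reads without molecular identifiers are not independent molecules. Libraries of one group were compared for duplicates over genes with at least 50 counts, and chi-square per degree of freedom lay between 17.3 and 68.5, so no pair was counted as 1. Pearson correlations of log2 CPM across genes, which are not independent replicates, were 0.977 to 0.990 within groups and 0.959 to 0.976 between them. The first 2 principal components held 54.8% and 18.1% of the variance.

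Genes were tested with edgeR 4.0.16 in R 4.3.3. Genes with enough counts by filterByExpr were kept, 13812 in all, which hold 99.88% of the counts. Libraries were scaled with TMM factors, and a robust quasi-likelihood fit with the fasting group as its only term gave 2-sided p-values. These were adjusted over all tested genes by the Benjamini-Hochberg method, with a threshold of 0.05, and the biological coefficient of variation was 14.3%. SE and 95% intervals of a log2 fold change came from the same fit. CPM values use the TMM-scaled library sizes, except those of lung genes, which use the plain totals.

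Gene lists were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2, a preset correlation of 0.01 between genes and at least 3 tested members, adjusted over 36 lists. Camera compares a list with all other genes. It was run again with a correlation estimated for each list, and fry, also from limma, tested whether the genes of a list move on balance one way, or in either direction, without comparing them with other genes. The 38 lists comprised 11 on sterol, bile acid, sphingolipid and fasting metabolism, 15 on other liver functions and states, and 12 of markers of other cell types, tissues or RNA quality. Lists, groups, tests, the rule for named genes and the alternatives were fixed before the data were examined, apart from those said to be chosen later.

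Named genes followed that rule. A set of 13 genes on sterol and fasting metabolism was always named. To these came the 8 largest rises and 8 largest falls among called genes with a mean of at least 10 CPM in the higher group and no overlap between the groups, leaving out pseudogenes and genes with no symbol or a placeholder name. For each of the first 11 lists the member with the largest rise, the largest fall and the highest mean CPM could be named, for each of the next 15 the 2 members with the smallest adjusted p, and for each marker list the most abundant member. Any other gene is said to be picked after its values were seen. Some genes that the rule names are not reported here.

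The scripts were tested on simulated data first, with counts drawn for the 13812 tested genes from the means and library sizes of these 6 libraries. Known changes were given to 200 genes. The filter, applied again to the simulated counts, left 13652 genes, and a few of the 200 fell under it. The comparison of 3 with 3 recovered 10.6% of 66 genes changed by 0.5 on the log2 scale, 65.2% of 66 changed by 1 and 92.3% of 65 changed by 2, with 7 false calls. A planted gene list was called and 0 of 20 random lists were. The simulated genes were drawn independently of each other, so this does not test false calls of lists whose genes vary together. In the simulation changes well under 2-fold were thus mostly missed. Its 200 changed genes are a far smaller share than the 18.7% of tested genes called here, which makes its adjusted threshold stricter. The recovery rates therefore do not carry over to these data, where the median size of a called change was 0.67. A gene that did not pass is still not shown to be unchanged.

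Alternatives were RLE and upper quartile scaling, no filter, a mean of at least 50 counts, DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out in turn, an adjusted p of 0.01, and a prior count of 0.5. Counts of list members and gene families without 4 h replicate 3 were added after that library was seen to stand apart. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.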

Results

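RNA sequencing of liver compared male C57BL/6J mice, a common inbred laboratory strain, after a short and after a long fast. The series is about cholesterol movement between membranes of the liver cell without vesicles, a task of the Aster proteins encoded by Gramd1a, Gramd1b and Gramd1c. All 6 livers were wild type, 3 taken after a 4 h fast and 3 after a 16 h fast. The labels give 3 mice per group, so each library is treated as 1 animal. Counts assigned to genes came to 26572532, 15173653 and 19706810 for replicates 1, 2 and 3 of the 4 h fast, and to 21825775, 16991034 and 25016855 for those of the 16 h fast. Between 19583 and 21980 genes had at least 1 count in a library. The albumin transcript Alb was the most abundant in each library, with 5.30% to 6.97% of gene counts, and mitochondrial transcripts took 4.98% to 6.01%. All changes below are 16 h relative to 4 h, as log2 fold change ± SE from 3 livers per group, and CPM values are mean ± SD (n = 3).

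The longer fast was marked by a rise of fatty acid oxidation genes and a fall of genes that make cholesterol and fatty acids. Camera called these 3 lists with its preset correlation, and none of them with an estimated one (adjusted p = 0.546 for each). The steepest rises with a mean of at least 10 CPM in the higher group were Fam107a (5.84 ± 0.79), Cyp4a14 (5.49 ± 0.31), Cyp4a10 (4.43 ± 0.32) and Cyp2b10 (3.50 ± 0.28). Cdkn1a, an inhibitor of cell cycle kinases, rose by 3.06 ± 0.56, Ehhadh, an enzyme of peroxisomal fatty acid oxidation, by 2.97 ± 0.22, the secreted lipocalin Lcn2 by 2.88 ± 0.24 and the steroid hydroxylase Cyp17a1 by 2.82 ± 0.17. Cyp4a14, a fatty acid hydroxylase, went from 146 ± 54.8 to 6568 ± 728 CPM, 45.0-fold, and its neighbour Cyp4a10 from 191 ± 85.1 to 4134 ± 292 CPM. The steepest falls were those of Chrna4, a subunit of the nicotinic acetylcholine receptor (-6.51 ± 0.71), Hcn3 (-4.45 ± 0.25), the fatty acid binding protein Fabp5 (-4.35 ± 0.30) and Thrsp, a regulator of fatty acid synthesis (-4.12 ± 0.35). Fam107a went from 0.224 ± 0.058 to 13.3 ± 7.8 CPM, and Chrna4 from 10.5 ± 6.1 to 0.107 ± 0.063 CPM. Each rests on very few counts in its lower group, so the size of its fold change is uncertain.

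Further down the ranking of falls came Hsd3b5 (-3.56 ± 0.42), the carbonic anhydrase Car3 (-3.45 ± 0.27), Clec2h (-3.28 ± 0.70) and Serpina7, the thyroxine-binding globulin (-3.26 ± 0.45). Among these 8 falls Car3 lost the most in level, from 3411 ± 246 to 311 ± 114 CPM. The edgeR adjusted p of these 16 genes lay between 6.11e-06 for Cyp17a1 and 0.0327 for Clec2h. The call of Fam107a was lost without 4 h replicate 2 or 3 (edgeR adjusted p = 0.0534 and 0.0691), and that of Cdkn1a without the same libraries (0.105 and 0.0677). Clec2h lost its call without 4 h replicate 2 or 3 (edgeR adjusted p = 0.0975 and 0.102) and without 16 h replicate 2 or 3 (0.0596 and 0.114). Hcn3 and Pklr overlap on opposite strands on chromosome 3, in 17.1% of the exon bases of Hcn3, so the value of Hcn3 is uncertain. Cyp4a10 and Cyp4a14, Cyp2b10 and Hsd3b5 are uncertain for another reason, as they belong to families of near-identical genes, and how reads common to such genes were handled cannot be read from the tables.

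**Figure D1:**
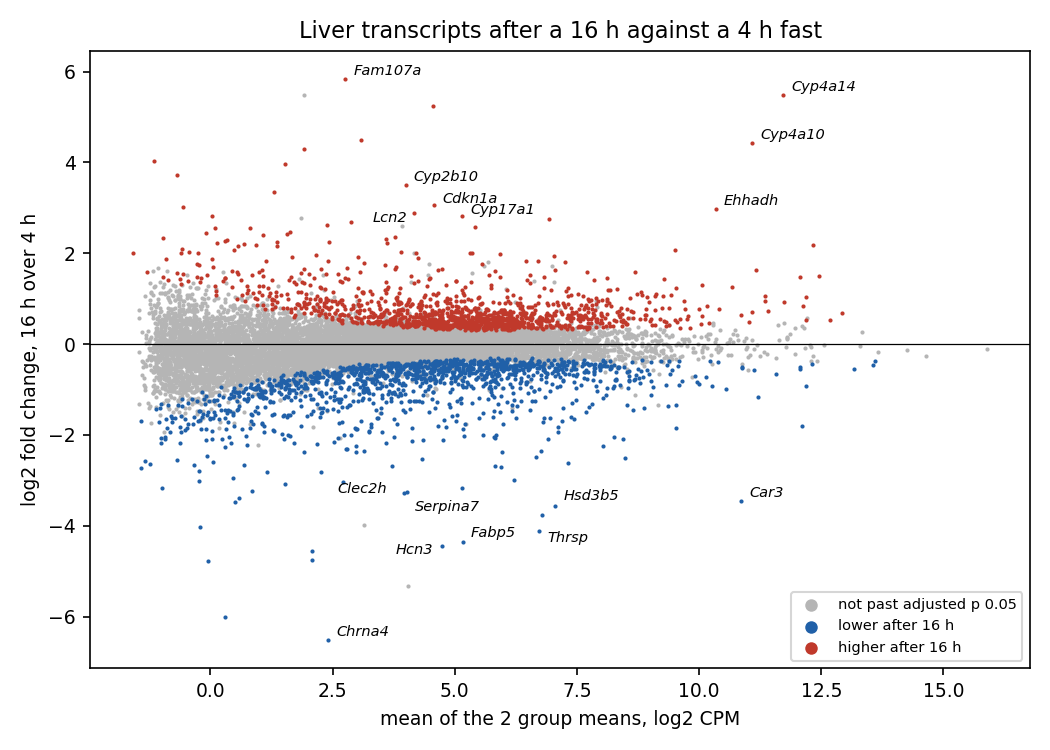
Each point is 1 of the 13812 genes tested, with the log2 of the mean CPM over both groups on the x axis and the log2 fold change of 16 h over 4 h on the y axis. Red points (1268 genes) were higher and blue points (1313 genes) lower after 16 h at an adjusted p of 0.05, grey points did not pass, and the labelled genes are the 8 largest rises and 8 largest falls among genes with a mean of at least 10 CPM in the higher group that met the rule for named genes, from Fam107a at 5.84 to Chrna4 at -6.51.

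Of the 13812 genes tested with edgeR, 1268 were higher and 1313 lower after 16 h, which is 18.7% of them. Among these, 243 were at least doubled and 418 at least halved, and the median size of the called changes was 0.67. The 3 values of one group lay entirely above or below those of the other for 5442 genes, or 39.4%, where chance gives 10%. Leaving out 16 h replicate 1, 2 or 3 left 818, 681 and 671 higher genes and 823, 715 and 696 lower ones. Replicate 3 of the 4 h fast stood apart on the second principal component, at -33.5 against 14.1 and 26.5 for its mates. The mean of its 3 tested neutrophil markers, of 10 listed, lay 2.97 log2 units above theirs. Csf3r, the most abundant of them, had a much smaller gap, at 2.455 CPM against 1.398 and 1.74 CPM. That library also carried transcripts of lung, such as Scgb1a1 at 92.4 CPM against at most 0.96 CPM in any other library. Without it, 1594 genes were higher and 1393 lower.

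The Aster genes did not pass the test. Gramd1a, on chromosome 7 at 31130127 to 31155896 of GRCm38, was at 19.97 ± 2.21 CPM after 4 h and 16.4 ± 1.9 CPM after 16 h (-0.29 ± 0.13, edgeR adjusted p = 0.15). Gramd1b, on chromosome 9 at 40293233 to 40531383, was near 1.36 ± 0.23 and 1.89 ± 0.61 CPM (0.47 ± 0.30, edgeR adjusted p = 0.30), with a change between 0.19 and 0.62 when single libraries were left out. Gramd1c, on chromosome 16 at 43980350 to 44063345, had the highest level of them, with 47.7 ± 8.8 and 41.5 ± 1.4 CPM (-0.20 ± 0.13, edgeR adjusted p = 0.32). The 95% intervals of the log2 change ran from -0.58 to 0.0011 for Gramd1a, from -0.19 to 1.14 for Gramd1b and from -0.49 to 0.093 for Gramd1c, so a doubling of Gramd1a or Gramd1c lies outside them. Gramd1c passed the test only when 4 h replicate 3, the library with lung transcripts, was left out (-0.33, edgeR adjusted p = 0.0135).

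Among 18 measured genes of nonvesicular sterol transport, none rose, 2 fell and 16 did not pass, and adjusted over the list alone the counts were 0 and 2. Stard4, a soluble sterol carrier, fell 3.11-fold from 115 ± 8.3 to 37.1 ± 6.0 CPM (-1.64 ± 0.13, edgeR adjusted p = 2.04e-05). The other was Npc2, a lysosomal cholesterol-binding protein named after its values were seen (-0.42 ± 0.12), a call lost without 4 h replicate 2 (edgeR adjusted p = 0.0659) or any one of the 16 h libraries (0.108, 0.114 and 0.113). Stard5 was 0.31 ± 0.10 higher without passing (edgeR adjusted p = 0.0547), with 23.9% of its exon bases overlapping other genes, and it passed without 4 h replicate 3 (0.0269). Without single libraries the number that fell was 4 without 4 h replicate 3, and 1 without 4 h replicate 2 or any one of the 16 h libraries. The list median was 0.0072 and its mean -0.040, camera placed it up and fry down, and neither called it (camera adjusted p = 0.775, fry adjusted p = 0.406).

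Cholesterol synthesis fell almost as a whole: of its 20 genes, 18 fell, 2 did not pass and none rose. The list median was -1.47 (camera adjusted p = 7.31e-12), against an adjusted p of 0.546 with an estimated correlation. Nsdhl, a sterol dehydrogenase on X at 72918557 to 72958514, fell 5.22-fold from 105 ± 12.1 to 20.03 ± 4.66 CPM (-2.38 ± 0.16, edgeR adjusted p = 1.09e-05). Fdps and Sqle, picked after their values were seen, fell by 2.38 and 2.01, Fdps with 26.7% of its exon bases overlapping another gene. Hsd17b7 was among the members that did not pass (0.31 ± 0.10, edgeR adjusted p = 0.0565), and it passed without 4 h replicate 3 (0.0373). The counts adjusted over the list alone were 18 fallers and 1 riser.

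Genes of sterol uptake and sensing moved both ways, with 2 of 12 rising, 3 falling and 7 not passing. The related regulators Insig1 and Insig2 split, Insig2 rising by 1.58 ± 0.24 and Insig1, picked after its values were seen, falling by 1.49. Srebf2, which encodes the main transcription factor of cholesterol synthesis genes, was at 58.1 ± 2.3 and 56.0 ± 4.6 CPM and did not pass (-0.05 ± 0.10, edgeR adjusted p = 0.763). The receptor Lrp1 did not pass either (-0.02 ± 0.12). The list as a whole was not called (median -0.037, camera adjusted p = 0.717), though fry gave an adjusted p of 0.0474 for lower. There were 2 risers and 4 fallers adjusted over the list alone.

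**Figure D2:**
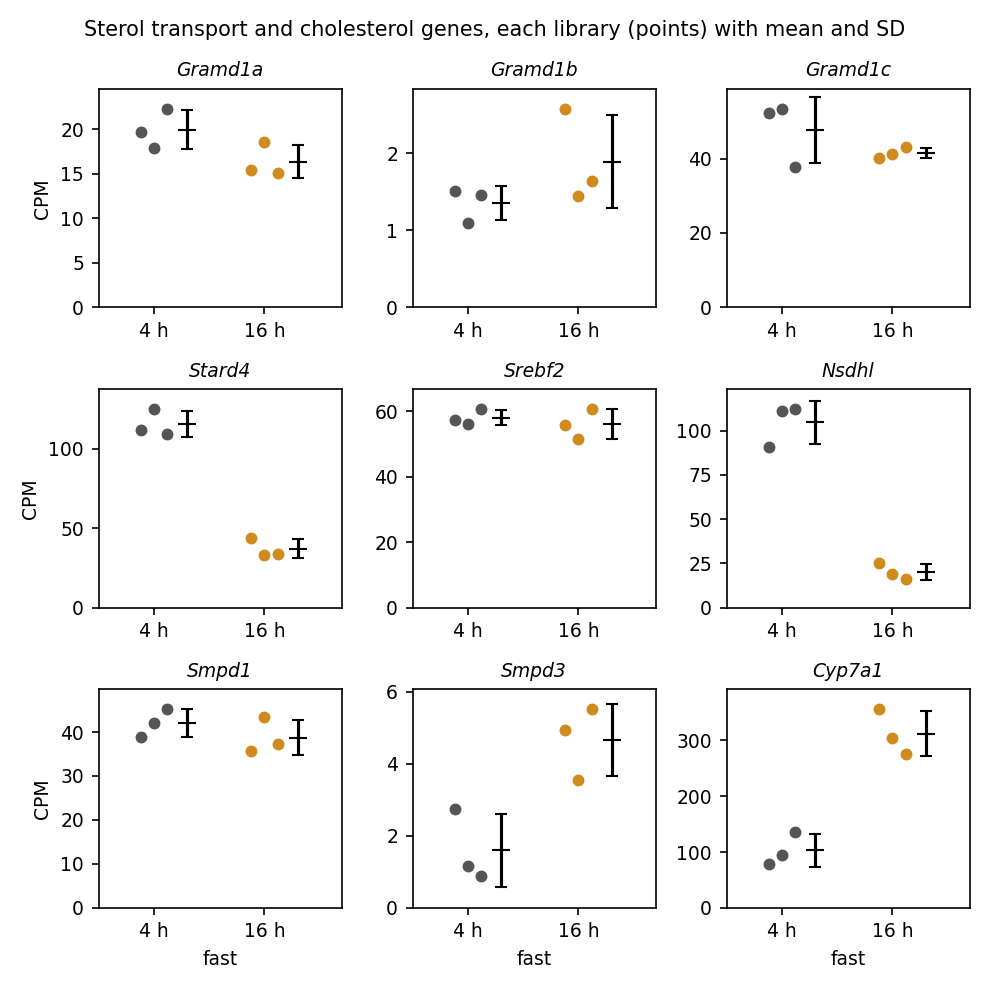
CPM of 9 sterol and sphingomyelin genes in each library, with 1 point per library, grey for the 4 h and orange for the 16 h fast, and the group mean with its SD as a bar beside the points. Gramd1a, Gramd1b, Gramd1c, Srebf2 and Smpd1 overlap or nearly touch between groups, while Stard4 and Nsdhl are lower and Smpd3 and Cyp7a1 are higher in each 16 h library.

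Cholesterol ester, efflux and lipoprotein genes were mixed, with 5 of 23 rising, 4 falling and 14 not passing (median -0.12, camera adjusted p = 0.775, with a median of -0.048 without 4 h replicate 3). Apoa4 rose 3.97-fold to 97.4 ± 35.1 CPM (1.99 ± 0.35), a call lost without 4 h replicate 2 or 3 (edgeR adjusted p = 0.0874 and 0.0961), and 69.8% of its exon bases overlap an antisense gene. Apoe, the most abundant member at 27817 ± 6102 and 23328 ± 1406 CPM, did not pass (-0.25 ± 0.15, and -0.048 without 4 h replicate 3). Of the falls, Angptl8 had the largest (-1.49 ± 0.36, and -0.93 without 4 h replicate 3) and lost its call without 16 h replicate 1, 2 or 3 (edgeR adjusted p = 0.0875, 0.0892 and 0.112). Risers numbered 3, 2, 2 and 3 without 4 h replicate 1 and 16 h replicates 1, 2 and 3, and fallers 7 without 4 h replicate 2 and 2 without 16 h replicate 3. Adjusted over the list alone, 7 rose and 6 fell.

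In the sphingomyelin and ceramide list 4 of 27 genes rose, 1 fell and 22 did not pass (median 0.039, camera adjusted p = 0.494), and the counts adjusted over the list alone were 4 and 1. Smpd1, the acid sphingomyelinase, did not pass, at 42.0 ± 3.2 and 38.7 ± 4.1 CPM (-0.12 ± 0.11, edgeR adjusted p = 0.502). Smpd3, a neutral sphingomyelinase, rose from 1.60 ± 1.01 to 4.67 ± 1.01 CPM (1.48 ± 0.36), a call lost without 16 h replicate 1 or 3 (edgeR adjusted p = 0.0511 and 0.0712). Without 16 h replicate 1, 2 or 3 the number that rose was 0, 2 and 0. The single fall, that of Asah1 (-0.49 ± 0.15), kept its call only without 16 h replicate 1. Without 4 h replicate 3, 2 members fell, but Asah1 was not among them (edgeR adjusted p = 0.0688). The ceramide synthase Cers2, the most abundant member, did not pass (-0.23 ± 0.10) except without 4 h replicate 3 (edgeR adjusted p = 0.0491).

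Bile acid genes included 7 of 21 that rose, 3 that fell and 11 that did not pass, and adjusted over the list alone 8 and 4. Cyp7a1, the rate-limiting enzyme of bile acid synthesis on chromosome 4 at 6265612 to 6275633, rose 3.02-fold from 103 ± 29.7 to 312 ± 40.5 CPM (1.60 ± 0.19, edgeR adjusted p = 4.05e-04). Cyp8b1, the sterol 12-hydroxylase gene picked after its values were seen, rose by 1.23 ± 0.11. Cyp2c70, which makes the muricholic acids of mice, fell from 496 ± 19.9 to 119 ± 16.9 CPM (-2.05 ± 0.13, edgeR adjusted p = 6.11e-06). Camera did not call the list (median 0.17, adjusted p = 0.136), while fry gave an adjusted p of 0.0149 for higher. Hsd3b7 had 0 of the 125286659 counts of all libraries, which allows up to 0.0239 CPM, and 99.2% of its exon bases overlap another gene, which can keep reads from being assigned.

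Fatty acid oxidation and ketogenesis rose: of 41 genes, 26 rose, 1 fell and 14 did not pass (median 0.83, camera adjusted p = 1.67e-14, and adjusted p = 0.546 with an estimated correlation). Cpt1a, which admits fatty acids to mitochondria, rose 2.07-fold from 398 ± 75.2 to 824 ± 66.8 CPM (1.05 ± 0.15, edgeR adjusted p = 6.89e-04). The exception was Fabp1, the liver fatty acid binding protein, which fell from 3264 ± 752 to 1462 ± 209 CPM (-1.16 ± 0.17). Fgf21, a fasting hormone of the liver, was at 2.56 ± 1.38 and 5.74 ± 2.16 CPM and did not pass (1.12 ± 0.39, edgeR adjusted p = 0.074), but it passed with DESeq2 (adjusted p = 0.0161) and, by edgeR, without 4 h replicate 1 (0.0112) or 16 h replicate 2 (0.0313). With values adjusted over the list alone, 30 rose and 2 fell.

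Gluconeogenesis had 6 of 13 genes rising, 7 not passing and none falling, with the same counts adjusted over the list alone. Pck1, which commits carbon to glucose synthesis, rose from 3055 ± 528 to 6265 ± 502 CPM (1.04 ± 0.14, edgeR adjusted p = 6.59e-04). Tat, a tyrosine aminotransferase, rose 3.12-fold (1.64 ± 0.22). The list median was 0.33 (camera adjusted p = 0.0018, and adjusted p = 0.546 with an estimated correlation), 0.70 without 4 h replicate 2 and 0.55 without 16 h replicate 1.

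Lipogenesis fell, with 13 of 19 genes lower, 6 not passing and none higher (median -0.91, camera adjusted p = 1.88e-07, and adjusted p = 0.546 with an estimated correlation). Srebf1, the gene of the lipogenic transcription factor SREBP-1, fell 5.09-fold from 182 ± 16.5 to 35.6 ± 7.7 CPM (-2.35 ± 0.16, edgeR adjusted p = 8.97e-06). Fasn, the fatty acid synthase, fell 4.77-fold from 434 ± 124 to 91.0 ± 14.4 CPM (-2.25 ± 0.20), and Thrsp fell from 199 ± 60.6 to 11.4 ± 4.2 CPM. Scd1, a desaturase and the most abundant member, fell from 6865 ± 3525 to 1962 ± 374 CPM (-1.81 ± 0.40). Its call was lost without 4 h replicate 2 (edgeR adjusted p = 0.111) and without 16 h replicate 1, 2 or 3 (0.0732, 0.0759 and 0.0615). In this list 13 fell and 1 rose when adjusted over the list alone.

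Glycolysis and glycogen genes split into 3 that rose, 8 that fell and 8 that did not pass, of 19, also when adjusted over the list alone. Pklr, the liver pyruvate kinase, fell 6.13-fold from 276 ± 87.5 to 44.9 ± 5.4 CPM (-2.62 ± 0.22, edgeR adjusted p = 7.37e-05), with 22% of its exon bases in overlap with Hcn3. Ldha rose by 0.63 ± 0.12 and Ppp1r3c, which targets a phosphatase to glycogen, by 0.89 ± 0.17, a call lost without 4 h replicate 3 (edgeR adjusted p = 0.054). The median was -0.12 (camera adjusted p = 0.119, fry adjusted p = 0.0086 for lower), and -0.21 without 16 h replicate 2.

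**Figure D3:**
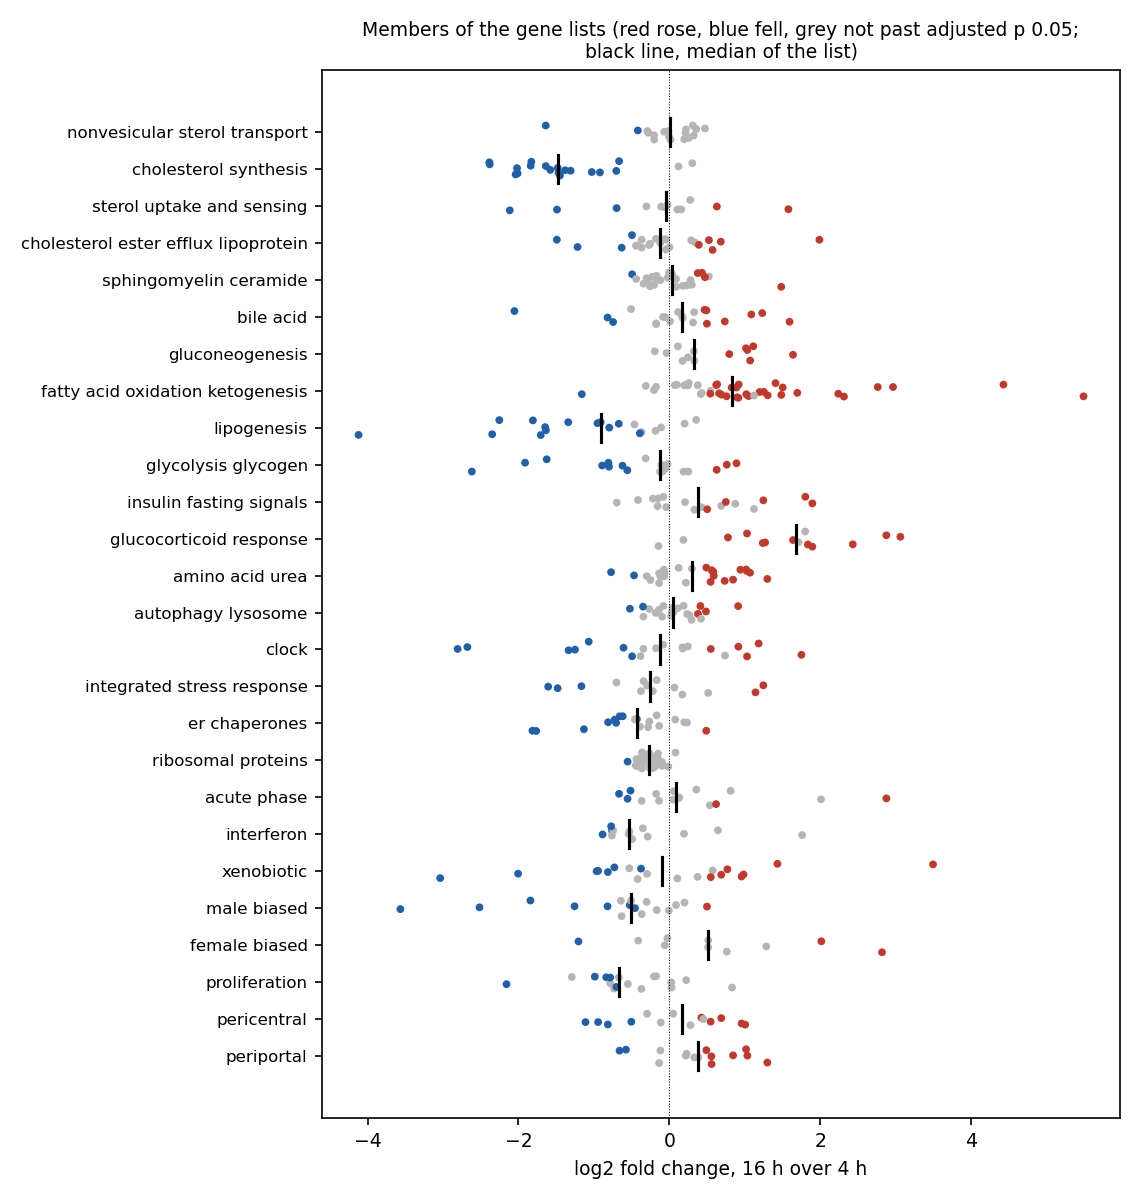
Each point is a measured member of a gene list fixed beforehand, marker lists left out, placed by its log2 fold change of 16 h over 4 h on the x axis, red where it rose, blue where it fell and grey where it did not pass an adjusted p of 0.05. The black line is the list median, which among the lists drawn is lowest for cholesterol synthesis (-1.47) and highest for the glucocorticoid response (1.68).

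Glucocorticoid response genes had the highest median, 1.68, with 10 of 14 rising, 4 not passing and none falling (camera adjusted p = 1.88e-07, and adjusted p = 0.546 with an estimated correlation). Lcn2 rose 7.36-fold from 4.37 ± 1.36 to 31.7 ± 7.4 CPM, and the kinase Sgk1 rose from 12.7 ± 2.0 to 30.4 ± 4.8 CPM (1.27 ± 0.16). Without 4 h replicate 2 the count was 6. Insulin and fasting signal genes held 5 of 18 that rose and 13 that did not pass (median 0.38, camera adjusted p = 0.0206, and adjusted p = 0.546 with an estimated correlation). Ddit4, an inhibitor of mTORC1 signalling, rose 3.72-fold (1.90 ± 0.36), a call lost without 4 h replicate 2 or 3 (edgeR adjusted p = 0.0793 and 0.0697). Igfbp2, the most abundant member, was 0.43 ± 0.18 higher without passing and passed without 4 h replicate 3 (edgeR adjusted p = 0.0011). That list lost its call without 4 h replicate 1 (camera adjusted p = 0.0816), and 3 members rose without 16 h replicate 3. In these 2 lists 12 and 7 genes rose and 0 fell when adjusted over the list alone.

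Amino acid and urea cycle genes rose in 12 of 25 cases, fell in 2 and did not pass in 11 (median 0.30, camera adjusted p = 0.0173, and adjusted p = 0.654 with an estimated correlation). Tdo2, which opens the tryptophan ring, rose from 1792 ± 180 to 3447 ± 542 CPM (0.94 ± 0.14), while Otc, a urea cycle enzyme, fell from 523 ± 44.6 to 307 ± 14.7 CPM (-0.77 ± 0.11). The call of the list was lost without 4 h replicate 1 (camera adjusted p = 0.0864) and without 16 h replicate 3 (0.0624), and the falls numbered 1 without 4 h replicate 2, 16 h replicate 1 or 16 h replicate 2. Autophagy and lysosome genes were not called as a list (median 0.047, camera adjusted p = 0.291, with a median of up to 0.12 without single libraries), with 4 of 22 rising, 2 falling and 16 not passing. Bnip3, a receptor for mitophagy, rose from 72.2 ± 6.3 to 136 ± 12.2 CPM (0.91 ± 0.11), and 22.3% of its exon bases overlap another gene. The lysosomal protease Ctsl, with 26.8% of its exon bases in overlap, rose by 0.49 ± 0.11, a call lost without 16 h replicate 3 (edgeR adjusted p = 0.0515). Between 1 and 7 members rose and between 0 and 2 fell over the fits without 1 library, 7 without 4 h replicate 3 and 1 without 16 h replicate 3. Risers and fallers numbered 13 and 2 for amino acid genes and 4 and 2 for autophagy genes when adjusted over the list alone.

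Clock genes changed in both directions: 5 of 20 rose, 7 fell and 8 did not pass, with the same counts adjusted over the list alone. Bhlhe41, a transcriptional repressor of the clock, fell from 8.41 ± 1.87 to 1.23 ± 0.54 CPM (-2.81 ± 0.30), with 19.0% of its exon bases in overlap, and its relative Bhlhe40 fell from 103 ± 9.9 to 41.0 ± 6.1 CPM (-1.33 ± 0.13, edgeR adjusted p = 7.35e-05). Picked after their values were seen, Arntl, a core activator of the clock, rose from 5.48 ± 2.33 to 18.5 ± 2.3 CPM (1.75 ± 0.27) and Dbp, one of its targets, fell from 98.0 ± 26.3 to 15.4 ± 5.2 CPM (-2.68 ± 0.28), with 18.0% of its exon bases in overlap. The list median was -0.13 (camera adjusted p = 0.589), and fry's test for change in either direction gave an adjusted p of 0.0012. Most other lists passed that test too, such as nonvesicular sterol transport (fry adjusted p = 1.663e-04), so it does not set the clock genes apart. Without 16 h replicate 3, 3 members rose. The labels give no time of day for the collection of either group.

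**Figure D4:**
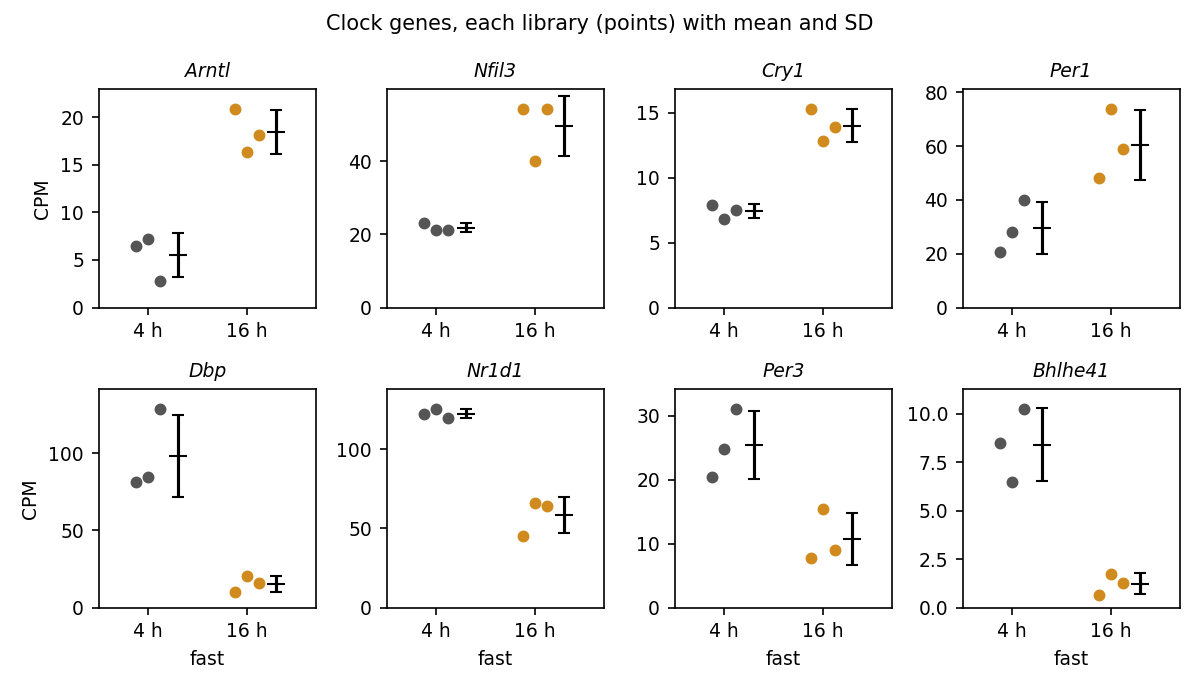
CPM of 8 clock genes in each library, with 1 point per library, grey for the 4 h and orange for the 16 h fast, and the group mean with its SD as a bar beside the points. Arntl, Nfil3, Cry1 and Per1 are higher and Dbp, Nr1d1, Per3 and Bhlhe41 lower in each 16 h library than in any 4 h library.

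Endoplasmic reticulum chaperones fell, with 9 of 19 lower, 1 higher and 9 not passing (median -0.43, camera adjusted p = 0.003, and adjusted p = 0.589 with an estimated correlation). Pdia6, a protein disulfide isomerase, fell from 378 ± 44.2 to 173 ± 12.7 CPM (-1.13 ± 0.12), and Xbp1, a transcription factor of the unfolded protein response, from 255 ± 11.9 to 166 ± 8.2 CPM (-0.62 ± 0.10). The member that rose was Dnajb9, named after its values were seen (0.49 ± 0.15), a call lost without 4 h replicate 2 or 3 (edgeR adjusted p = 0.0581 and 0.0665) or 16 h replicate 2 or 3 (0.192 and 0.0929). Genes of the integrated stress response were not called as a list (median -0.26, camera adjusted p = 0.642, fry pointing up), with 2 of 14 rising, 3 falling and 9 not passing. Atf5 rose from 279 ± 21.3 to 616 ± 39.5 CPM (1.14 ± 0.11), and Sesn2, a stress-induced inhibitor of mTORC1, by 1.25 ± 0.13. A single member fell without 16 h replicate 1. Chaperones had 1 riser and 11 fallers, and stress response genes 2 and 3, when adjusted over the list alone.

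Ribosomal protein genes had a median of -0.26 (camera adjusted p = 0.0046, and adjusted p = 0.756 with an estimated correlation), though 1 of 36 fell and 35 did not pass. The number that fell was 4 without 4 h replicate 1 or 2 and 0 without any one of the 16 h libraries. None rose or fell when adjusted over the list alone. Rplp1 fell from 346 ± 84.7 to 236 ± 3.1 CPM (-0.55 ± 0.15, and -0.32 without 4 h replicate 3), a call lost without 16 h replicate 1, 2 or 3 (edgeR adjusted p = 0.091, 0.101 and 0.09), and Rpsa did not pass (-0.43 ± 0.14, edgeR adjusted p = 0.0507), though it passed without 4 h replicate 1 or 2 (0.0434 and 0.0402) and under several other settings. The mean of the list in 4 h replicate 3 lay 0.47 log2 units above its mates, and without that library the median was -0.089 and the call was lost (camera adjusted p = 0.208).

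Acute phase genes were not called as a list (median 0.096, camera adjusted p = 0.717), with 2 of 16 rising, 3 falling and 11 not passing, also when adjusted over the list alone. Fgg, the fibrinogen gamma chain, fell from 3732 ± 262 to 2354 ± 63.8 CPM (-0.67 ± 0.11). Without 16 h replicate 1 or 3, 1 member fell. The acute phase mean of 4 h replicate 3 was 0.58 log2 units above its mates. Interferon-response genes had a median of -0.53 (camera adjusted p = 0.0287, and adjusted p = 0.654 with an estimated correlation), with 3 of 13 lower and 10 not passing, 4 lower when adjusted over the list alone. Ifit3, an antiviral effector, fell from 10.4 ± 2.1 to 5.64 ± 1.98 CPM (-0.88 ± 0.24). Its call and that of the list were lost without 4 h replicate 1 or 3 or 16 h replicate 2 or 3, with camera adjusted p of 0.0816, 0.108, 0.147 and 0.101 and edgeR adjusted p of 0.0801, 0.0904, 0.0988 and 0.106. Members that fell then numbered 0, 1, 0 and 0.

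Xenobiotic metabolism genes rose and fell in equal number, 7 each of 20, with 6 not passing (median -0.093, camera adjusted p = 0.985). Cyp2b10 rose 11.3-fold from 2.59 ± 0.88 to 29.3 ± 8.9 CPM, while Cyp2c55 fell 8.21-fold from 11.8 ± 2.8 to 1.40 ± 0.43 CPM (-3.04 ± 0.25). Adjusted over the list alone, 7 rose and 8 fell. Of 17 genes with higher expression in male than in female liver, 7 fell, 1 rose and 9 did not pass (median -0.51, camera adjusted p = 0.003, and adjusted p = 0.547 with an estimated correlation). The male-biased median was -0.28 without 4 h replicate 3, and the single rise was lost without 16 h replicate 3 and became 2 without 4 h replicate 3. Nudt7, a peroxisomal hydrolase, fell from 606 ± 98.0 to 106 ± 9.9 CPM (-2.52 ± 0.14), and Cyp2u1 fell by 1.26 ± 0.14. Of 10 female-biased genes 2 rose, 1 fell and 7 did not pass (median 0.52, camera adjusted p = 0.0837), the rise led by Cyp17a1 and the fall that of Cyp2c40 (-1.20 ± 0.24), a member of a near-identical family. The mean of this list in 4 h replicate 3 was 1.45 log2 units below its mates (-1.45). Without that library the median was -0.015, and the list passed without 4 h replicate 2 (camera adjusted p = 0.0184) or 16 h replicate 3 (0.0459). When adjusted over the list alone, 1 male-biased gene rose and 8 fell, and 2 and 1 female-biased genes did.

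Proliferation genes fell in 5 of 17 cases and 12 did not pass (median -0.67, camera adjusted p = 0.0152, and adjusted p = 0.58 with an estimated correlation). Ccnd1, the gene of cyclin D1, fell 4.46-fold from 9.43 ± 3.70 to 2.08 ± 0.76 CPM (-2.16 ± 0.33), with 23.4% of its exon bases overlapping another gene. The list lost its call without 16 h replicate 1 (camera adjusted p = 0.0696), and its median was -0.40 without 4 h replicate 2. Members that fell numbered 2, 2 and 8 without 4 h replicates 1, 2 and 3, and 1, 3 and 3 without 16 h replicates 1, 2 and 3. Adjusted over the list alone, 6 fell and 1 rose. Genes expressed mainly near the portal vein rose in 7 of 15 cases, fell in 2 and did not pass in 6 (median 0.39, camera adjusted p = 0.0162, and adjusted p = 0.622 with an estimated correlation). Of these, Hal, Gls2, Arg1, Ass1, Cps1, Uroc1, Asl and Gldc are also in the amino acid and urea cycle list. Pck1 and Sds are also in the gluconeogenesis list, so the call of the portal list is not independent of theirs. Asl, a urea cycle enzyme, rose 2.46-fold from 618 ± 156 to 1521 ± 276 CPM (1.30 ± 0.19). The call of the portal list was lost without 4 h replicate 1 (camera adjusted p = 0.0821), its median was 0.59 without 4 h replicate 2 and 0.23 without 16 h replicate 2, and the falls numbered 0 or 1 without 16 h replicate 1, 2 or 3 or 4 h replicate 2 or 3. Genes expressed near the central vein split into 5 that rose, 4 that fell and 5 that did not pass, of 14 (median 0.17, camera adjusted p = 0.494), with 3 rising without 4 h replicate 1, 16 h replicate 1 or 16 h replicate 3. Ahr (1.01 ± 0.12) and the nuclear receptor Nr1i3 (0.96 ± 0.11) rose, Nr1i3 with 74.9% of its exon bases overlapping an antisense neighbour. Both zonation lists kept these counts, 7 and 2, and 5 and 4, when adjusted over the list alone.

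Markers of other cell types were mostly lower or did not pass. In the stellate cell and fibroblast list 3 of 13 fell and 10 did not pass (median -0.36, camera adjusted p = 0.0287, and adjusted p = 0.654 with an estimated correlation). The 3 were the collagens Col1a1 (-1.46 ± 0.25) and Col3a1 (-1.70 ± 0.27) and the smooth muscle actin Acta2 (-2.22 ± 0.32), named after their values were seen. Dcn, the most abundant marker, did not pass (0.11 ± 0.15). The call of this list was lost without 4 h replicate 1 (camera adjusted p = 0.0949) or 16 h replicate 2 (0.12, with a median of -0.19), and 5 members fell without 16 h replicate 1. Red blood cell markers had a median of -0.84 (camera adjusted p = 0.0287, and adjusted p = 0.622 with an estimated correlation), with 1 of 5, Alas2, falling (-1.09 ± 0.11, 15.5% of its exon bases in overlap). The red cell call was lost without 4 h replicate 1 or 3 (camera adjusted p = 0.0862 and 0.0592) or 16 h replicate 1 (0.0813, with a median of -0.41), and 2 markers fell without 4 h replicate 2.

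The adipose list held Car3, Cfd and Lipe, and all 3 measured members fell (median -2.66, camera adjusted p = 0.0111, and adjusted p = 0.546 with an estimated correlation), with 1 falling without 16 h replicate 2 and a median of -1.69 without 4 h replicate 1. Cfd lost its call without 4 h replicate 3 or any one of the 16 h libraries (edgeR adjusted p between 0.0522 and 0.0762), and Lipe, with 15.6% of its exon bases in overlap, without 16 h replicate 2 (0.0848). The other members Adipoq, Plin1 and Retn were at 0.0552, 0.0593 and 0.0245 CPM after 4 h, and Lep had 0 of 61452995 counts, which allows up to 0.0488 CPM. Sinusoidal endothelial markers (13, led by Eng at -0.23 ± 0.11), cholangiocyte markers (7, Spp1 -0.46 ± 0.18, with 18.8% of its exon bases in overlap), B and plasma cell markers (5, Ighm -0.99 ± 0.35) and mitochondrially encoded genes (12, mt-Co1 -0.12 ± 0.12) had no member past the threshold by edgeR. Their medians were -0.13, -0.41, -0.89 and -0.047 (camera adjusted p = 0.89, 0.494, 0.115 and 0.797). The cholangiocyte median was -0.0048 without 4 h replicate 3, and the endothelial one -0.027 without 4 h replicate 1 and -0.026 without 16 h replicate 2. Ighm passed without 16 h replicate 1 (edgeR adjusted p = 0.0016), and the B and plasma cell list passed without that library or without 4 h replicate 2 (camera adjusted p = 0.0161 in both fits).

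Of 12 Kupffer cell markers 1 fell, Timd4, named after its values were seen (-0.85 ± 0.25), and 11 did not pass (median -0.26, camera adjusted p = 0.167), among them Clec4f (-0.60 ± 0.20). Timd4 kept its call only without 4 h replicate 1, with edgeR adjusted p between 0.0724 and 0.132 in the other 5 fits without 1 library. Without 4 h replicate 2 the list passed (camera adjusted p = 0.0115) with 3 members lower, among them Clec4f (edgeR adjusted p = 0.004). Without 4 h replicate 3 the median was -0.13 (camera adjusted p = 0.833) and the change of Clec4f -0.35. None of 3 neutrophil markers passed, Csf3r at -0.92 ± 0.38 among them (median -1.74, camera adjusted p = 0.58), and without 4 h replicate 3 the median turned to 0.84. In that library the Kupffer, cholangiocyte and B cell means lay 0.60, 0.53 and 0.58 log2 units above its mates. Of 9 immediate-early genes Egr1 (-2.10 ± 0.40) and Fos (-1.14 ± 0.31), named after their values were seen, fell and 7 did not pass (median -0.50, camera adjusted p = 0.136), with Zfp36 at 0.23 ± 0.25, and 1 or 0 fell without any single library except 16 h replicate 1. Egr1 lost its call without 4 h replicate 3 or 16 h replicate 2 or 3, and Fos without 4 h replicate 1 or 2 or 16 h replicate 2 or 3. A single T cell marker, Cd4 (-1.10 ± 0.44), and a single pancreatic marker, Cela1 (-1.77 ± 0.21, edgeR adjusted p = 3.37e-04), reached the depth needed for testing. Cd4 passed without 16 h replicate 3 (edgeR adjusted p = 0.0355). Adjusted over the list alone, 3 B cell, 3 stellate, 3 adipose, 2 immediate-early, 1 red cell, 1 T cell and 1 pancreatic marker fell and no Kupffer, endothelial, cholangiocyte, neutrophil or mitochondrial one did.

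Without 4 h replicate 3, 1 gene rose in each of the nonvesicular transport, cholesterol synthesis, Kupffer and endothelial lists, where none did with all 6 libraries. Without 4 h replicate 1, 1 insulin and fasting signal gene fell, and without 16 h replicate 1, 1 proliferation gene rose. Camera with its preset correlation called 6 lists higher and 10 lower of 36 tested. With an estimated correlation no list was called, while fry called 12. The 6 livers allow 10 splits into groups of 3, and the other 9 splits called between 3 and 17 lists by camera.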

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

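Counts of list members and of gene families without 4 h replicate 3 were chosen only after the data were seen, and the other alternatives were planned. RLE scaling (1324 higher, 1285 lower), no filter (1558 and 1555), a mean of at least 50 counts (1195 and 1233), DESeq2 (1410 and 1279, with no adjusted p for 12999 genes) and limma-voom (1277 and 1280) kept the counts of called genes within 1.5 times those given. Upper quartile scaling moved the median of all genes by -0.05 and gave 1031 higher and 1596 lower genes, so 39.2% of calls were higher in place of 49.1%. Every called gene that these fits tested kept its direction. At an adjusted p of 0.01 there were 539 higher and 592 lower genes. The filter on a mean of 50 counts left 264 genes at least halved, since it tests fewer genes. With an estimated correlation camera called 0 lists higher and 0 lower. Only the correlation setting differs between these runs, with estimates such as 0.83 for ribosomal and 0.43 for cholesterol synthesis genes in place of 0.01. The calls with the preset value therefore rest on taking the genes as nearly independent. Fry called 5 higher and 7 lower.

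Leaving out 1 library at a time gave 671 to 1594 higher genes, 696 to 1393 lower genes and 3 to 7 lists higher. Each of these fits has 1 library fewer, so the number of samples does not account for the spread between them. The lower ends of the gene counts came without 16 h replicate 3 and the upper ends without 4 h replicate 3. Some values changed sign in these fits. Dcn ranged from -0.0119 to 0.2628, Lrp1 from -0.1 to 0.074 and Srebf2 from -0.111 to 0.007. List medians ranged from -0.0165 to 0.0866 for nonvesicular sterol transport, from -0.0535 to 0.016 for sterol uptake, from -0.1859 to 0.0506 for clock genes and from -0.2571 to 0.2147 for the acute phase. They ranged from -0.1695 to 0.1823 for xenobiotic metabolism, from -0.015 to 0.7816 for female-biased genes, from -2.277 to 0.8359 for neutrophil markers and from -0.1628 to 0.0182 for mitochondrial genes. With a mean of at least 50 counts the medians of nonvesicular sterol transport (-0.0046), xenobiotic metabolism (0.0954) and cholangiocyte markers (0.0596) also changed sign, over fewer genes. None of these genes or lists was called by edgeR or camera with all 6 libraries. In fits without 1 library other uncalled values kept their sign but moved by more than 1.5 times. List medians ranged up to 0.0965 for sphingomyelin and 0.2731 for pericentral genes, down to 0.1082 for bile acid genes, and as near 0 as -0.1658 for the integrated stress response and -0.2712 for immediate-early genes. Fgf21 ranged up to 1.7025, Igfbp2 to 0.6893 and Zfp36 from 0.0538 to 0.5162. Cd4 ranged from -1.7406 to -0.7518, Ighm from -1.6364 to -0.7164 and Csf3r from -1.2475 to -0.594. Rpsa came as near 0 as -0.2404, Spp1 as -0.2172, Gramd1c as -0.0951, Smpd1 as -0.0501 and mt-Co1 as -0.0468. The filter on a mean of 50 counts also left 7 lists lower in place of 10, as the interferon and stellate lists lost their calls (camera adjusted p = 0.157 and 0.0673) and the adipose list kept fewer than 3 members.

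Some named calls depended on the tool or setting. Without a filter Apoa4, Cdkn1a, Clec2h and Scd1 were not called (edgeR adjusted p = 0.0793, 0.0724, 0.099 and 0.141). The same fit called Cd4, Clec4f, Fgf21, Igfbp2, Ighm, Rpsa and Spp1 (edgeR adjusted p = 0.0091, 1.605e-04, 2.441e-05, 0.0054, 2.690e-04, 0.0168 and 0.0127). Fgf21, Ighm, Rpsa, Stard5 and Clec4f were called by DESeq2 (adjusted p = 0.0161, 0.032, 0.0247, 0.0182 and 0.022), and Ighm and Stard5 by limma-voom (0.0321 and 0.0499). Stard5 was also called with RLE scaling (edgeR adjusted p = 0.0485), Clec4f and Rpsa with upper quartile scaling (0.0457 and 0.0318), and Rpsa and Stard5 with a mean of at least 50 counts (0.045 and 0.0498). The cause was not tested. The lists of amino acid, ribosomal, interferon, proliferation, periportal, stellate and red cell genes were not called by fry (adjusted p between 0.0824 and 0.328).

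The groups share replicate numbers, and libraries with the same number had deviation correlations of 0.0876, 0.0933 and 0.0455. Pairs with unlike numbers ranged from -0.1383 to 0.0662. The values of the same number were higher on the whole but small, so they neither show a pairing of mice nor exclude one. As a hint from the data only, 16 h replicate 3 correlated best with 4 h replicate 1 (0.0662) and the others with their own number. A fit with the replicate block gave 1352 higher and 1396 lower genes, 2748 in all, of which 2451 were shared with the fit without it, each in the same direction. Under the block Cdkn1a, Clec2h and Scd1 (edgeR adjusted p = 0.108, 0.125 and 0.108) and the red cell list (camera adjusted p = 0.0606) were not called. Fgf21, Ighm, Rpsa and Spp1 were (edgeR adjusted p = 0.0068, 0.0182, 0.0394 and 0.0221), and no other call of a named gene or list changed. With 3 mice per group the simulation recovered 10.6% of changes of 0.5 on the log2 scale. Far fewer genes were changed in it than were called here, so that rate does not carry over, but small changes can still be missed.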

Other observations

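The tests of gene families, of time of day, of adipose tissue and of male-biased and female-biased genes were chosen only after the result was seen, and the rest were fixed before it. Genes that share a symbol root fell or rose together in several families with at least 10 tested members, by a 1-sided Fisher's exact test adjusted over 316 tests of 158 families. This test treats genes as independent. Family members can vary together across the same livers, so its p-values do not measure variation between mice. Carboxylesterases (Ces), which split esters in lipids and drugs, had 11 of 15 members lower and 1 higher (adjusted p = 1.657e-06). Among them Ces3a fell from 2210 ± 144 to 1530 ± 20.6 CPM (-0.53 ± 0.11) and Ces3b from 657 ± 93.4 to 377 ± 49.9 CPM (-0.80 ± 0.14). Genes of the major histocompatibility complex (H2-) were lower in 11 of 22 cases (adjusted p = 2.280e-04), 7 without 16 h replicate 1. Those that present antigen on macrophages and B cells led them, H2-Ab1 at -1.15 ± 0.14, H2-Eb1 at -1.12 ± 0.18 and H2-Aa at -1.08 ± 0.19, and the abundant H2-Q10 fell by 0.58 ± 0.13, a call lost without 16 h replicate 1 (edgeR adjusted p = 0.0652). The markers of those cells lay lower too without being called (median -0.89 for B and plasma cells and -0.26 for Kupffer cells), and in 4 h replicate 3 they stood 0.58 and 0.60 log2 units above its mates. Without 4 h replicate 3, 10 of the 22 H2- genes were still lower. H2-Ab1, H2-Eb1 and H2-Aa then kept their calls (edgeR adjusted p = 2.04e-04, 0.0041 and 0.01), so these falls did not rest on that library alone. How reads common to near-identical family members were handled cannot be read from the tables, so counts within a family are uncertain.

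Acyl-CoA thioesterases (Acot) rose in 6 of 11 cases (adjusted p = 0.0144), with Acot1 going from 31.2 ± 8.3 to 212 ± 28.8 CPM (2.76 ± 0.18). Hydroxysteroid dehydrogenases (Hsd) fell in 6 of 13 cases and rose in 4 (adjusted p = 0.0314 for lower), Hsd17b6 from 195 ± 30.7 to 45.8 ± 4.9 CPM (-2.09 ± 0.14). Aldo-keto reductases (Akr) fell in 6 of 13 cases (adjusted p = 0.0314), 3 without 16 h replicate 2, with Akr1c6 at -1.35 ± 0.14. Serpins of clade A fell in 7 of 18 cases (adjusted p = 0.0338), Serpina6, the corticosteroid-binding globulin, by 1.72 ± 0.11. Cytochrome P450 genes (Cyp) were enriched both ways, 19 higher and 17 lower of 72 (adjusted p = 0.0019 and 0.0208). Interferon-induced Ifi genes fell in 6 of 14 cases (adjusted p = 0.0393), but in 0 to 3 cases with any one library left out. The smallest p of all genes was that of Aacs, which activates acetoacetate for lipid synthesis and fell from 64.0 ± 8.1 to 7.17 ± 0.90 CPM (-3.17 ± 0.14, edgeR adjusted p = 9.44e-07). The methyltransferase Inmt fell from 564 ± 62.3 to 132 ± 26.9 CPM (-2.10 ± 0.16), and both kept their calls without any single library.

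Of the 10 splits of the 6 libraries into groups of 3, the real one called 2581 genes and the highest of the others 0, so 1 of 10 gave as many. For gene lists the real split called 16 and the highest of the others 17, so 2 of 10 gave as many. With 10 splits the share cannot be under 0.05.

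The fall of cholesterol synthesis and lipogenesis genes was weighed first, with a median of -1.38 over 39 members. Removing the trend of fold change with GC content and transcript length left it at -1.3731, which argues against that trend as its cause. A lower share of hepatocyte RNA after 16 h would lower these members and abundant liver transcripts alike, but 114 nuclear genes with at least 1000 CPM had a median of 0.0475. Scaling of the libraries keeps such a median near 0, so it cannot by itself test that share. The 39 members fell relative to the abundant genes, which a loss common to both would not produce. No single library decided the fall, since the median was at most -1.3108 without any of them. A response of both pathways to the longer fast may therefore underlie it, as a hypothesis, and time of day at collection stays open because the labels do not give it.

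Clock genes were weighed next. Genes that peak around the start of the light phase (Arntl, Clock, Npas2, Nfil3) had a median of 0.96 and 7 that peak later one of -0.49, a difference of 1.4549. Such a gap could come from collection at different times of day or from the fast itself, and these cannot be told apart without the hour of collection. All 12 called clock genes kept their sign in each of the 6 fits without 1 library. Every called gene tested in those fits did so too, so this cannot tell whether 1 library decides the pattern. Between 3 and 5 clock genes were called higher and 6 or 7 lower in these fits.

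Transcripts of other tissues were weighed last. In 4 h replicate 3, Scgb1a1 (92.4 CPM), Sftpc (46.4 CPM), Sftpa1 (16.5 CPM), Cbr2 (12.6 CPM) and Sftpb (9.13 CPM) stood above every other library, where they reached at most 0.96, 1.53, 3.25, 0.26 and 0.32 CPM. Of 17 further lung genes listed before their values were looked at, 13 (76.5%) were highest in that library. An equal chance for each library would give 16.7%. That rate does not hold for genes that differ between the fasts, such as Inmt, or that vary together, so it is a rough guide only. Only 7 were at more than 2 times the next library, with Inmt, also abundant in liver, at 1.14 and Pdpn at 1.21. All 15 counts of Nkx2-1 and all 14 of Scnn1g lay in 4 h replicate 3, while 4 of all 25 listed genes exceed 10 CPM in other libraries too. RNA from lung tissue at dissection or reads from a lung library are candidate sources, which predict the same values, and no biological explanation was tested. Adipose tissue on the 4 h livers is argued against as a cause of the lower Car3, since the highest of Adipoq, Plin1, Lep and Retn reached 0.0017 CPM per 100 CPM of Car3.

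A further hypothesis was that the longer fast shifts male-biased and female-biased liver genes in opposite directions. Fry from limma was run on each list alone. The male-biased list, with a median of -0.51, gave a p of 0.0055, and between 0.0014 and 0.0271 without single libraries. The female-biased list, with a median of 0.52, gave 0.0717, between 0.0222 and 0.233 without single libraries, and its median was -0.015 without 4 h replicate 3. An opposite shift of the female-biased genes was therefore not shown, and it is not excluded either.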
